A study of Nostoc punctiforme PCC 73102 with 4 samples.

How the data were processed

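Cappable-seq libraries were made from total RNA of developing hormogonia of Nostoc punctiforme, 6 h after 4 mM sucralose, which holds back their development, had been washed out. Per the labels, the wild type and the sigJ, sigC and sigF deletion strains each gave 1 biological replicate, grown without fixed nitrogen, and single reads of 75 bp came from 1 lane of a NextSeq instrument. Per the submitters' processing notes, reads were aligned with Bowtie2; the version, the settings, the rule for calling transcription start sites (TSSs) and the definition of the score are not given in the sources used here.

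The table deposited by the authors lists 12660 TSSs on the chromosome and 5 plasmids, with replicon, position, strand and, for each library, a relative read score. The deposited scores were used as RPM, the reads at a TSS scaled to the total reads of its library. This unit was inferred: every score is a whole multiple, within 0.01 read, of a constant step per library that corresponds to 1 read. The library totals implied by these steps are 8325206 reads for the wild type, 8520542 for sigJ, 7707859 for sigC and 9013364 for sigF. The listed TSSs hold 74.8%, 64.9%, 70.4% and 68.0% of them. The smallest wild-type value is 5.05 RPM (42 reads), so TSSs were listed by their wild-type level. The smallest values above 0 in the deletion libraries are 1.06, 1.04 and 1.11 RPM (9, 8 and 10 reads), and 601, 564 and 63 TSSs are listed at 0 there. A listed 0 was read as below the smallest listed value of its library, and folds against it are given as at least the ratio to that value.

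Gene positions came from an annotation table of the same assembly, with 7724 genes, of which 927 have a symbol. Strand was taken from the letter in the older locus tag, which gave an orientation to 6826 genes; the other 898 were left out of the assignment. A TSS was assigned to the nearest gene starting 0 to 300 nt downstream on its strand, and otherwise classed as inside a gene, antisense to a gene, or elsewhere. As a check on strand and coordinates, 49.0% of 6205 chromosomal genes had a TSS in this window on their own strand, against 25.1% on the other strand. In all, 3138 genes had an upstream TSS, 542 of them with a symbol.

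For each TSS the log2 ratio of each deletion strain to the wild type was computed after adding 1 RPM to both values. A TSS was called lower or higher at a log2 ratio of at least 2 in size with at least 5 RPM in the higher library. With 1 library per strain there was no test across replicates. Folds carry 95% intervals from the exact conditional binomial for a pair of Poisson counts, which cover counting error only. Overlaps between strains are given beside the number that independent calls would share. A planned simulation of unchanged libraries held counting error alone, under which no TSS is called, so it gave no baseline for the overlaps.

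The genes named were fixed by a rule before the values were seen: the sigma factor genes; among called TSSs upstream of genes with an informative product name, the 12 largest falls and 8 largest rises per strain; the 2 genes of each list with the largest change; and the 5 strongest TSSs lower in every strain. The annotation used here holds no product names, so a gene symbol stood in for them, and for SigF only 3 falls and 3 rises had one. Genes named beyond the rule, including list members given as examples and the strongest TSSs of each pattern of strains, were chosen after their values were seen. Values summed over all upstream TSSs of a gene are given where they tell another story than the single TSS.

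Gene lists were written before the values were seen. Because their patterns relied on product names, they were rewritten as symbol patterns and older locus numbers after the symbols in the annotation were seen and before any ratio was computed. This step added a list of NADH dehydrogenase-like and cytochrome genes and wall synthesis genes to the division list, and left no usable list for glycosyltransferases or cyclic-di-GMP. Of 19 lists, 11 had at least 3 genes with an upstream TSS. For these the median log2 ratio of summed upstream values was placed among 10000 random lists. Each gene was replaced by a draw from itself and the 50 nearest on either side in mean level. Near the top or bottom of the ranking, the end gene filled the missing places. No gene was in more than 1 list. tRNA genes have no orientation in the annotation, and 0 were measured.

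Runs along the chromosome were sought with a running median over 15 neighbouring TSSs of the log2 ratio, less the median of the replicon, keeping windows below -1.3, and the longest unbroken series of TSSs at least 2-fold lower within the longest run set its edges; this scan was chosen after the values were seen. Alternatives changed the pseudocount (0.1 or 5), the minimum level (none or 20 RPM), the fold (2 or 8), the scaling (median of ratios, or totals without the strongest 1% of TSSs) and the unit counted (genes by sum, strongest TSS per gene, upstream TSSs only). The steps were tested on simulated data with 12660 TSSs, 200 of them changed: 0 unchanged TSSs were called, falls of 16-fold were recovered in 100%, 100% and 90% of cases for sigJ, sigC and sigF, falls of 8-fold in 96%, 88% and 84%, and rises in 100%. These simulated data held counting error alone, under which no unchanged TSS is called. They gave no rate of false calls from variation between cultures or libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Promoter sequence features were planned but left out because they need the genome sequence.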

Results

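Nostoc punctiforme is a filamentous, nitrogen-fixing cyanobacterium whose filaments can turn into hormogonia, short-lived motile filaments that glide by type IV pili. Sigma factors are the RNA polymerase subunits that recognise promoters, and SigJ, SigC and SigF act during this development. The comparisons asked which transcription start sites (TSSs) need each of these factors in developing hormogonia. Cappable-seq, which enriches RNA with a 5'-triphosphate and so marks where transcription began, was done on the wild type and on strains with sigJ, sigC or sigF deleted. There was 1 library of 1 culture per strain, so no replicate check was possible. Intervals given with folds cover counting error only. All strain values are in RPM, in the order wild type, sigJ, sigC and sigF deletion wherever 4 are listed.

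The wild type had 12660 TSSs, each at 5.05 RPM or more. Of these, 4497 (35.5%) lay within 300 nt upstream of a gene on the same strand, 3231 (25.5%) inside a gene, 2934 (23.2%) antisense to a gene and 1998 (15.8%) elsewhere. The chromosome carried 11975 of them, and the plasmids pNPUN01 to pNPUN05 carried 286, 176, 113, 75 and 35. The strongest TSS, 75 nt inside Npun_F5190 on the chromosome (6426388, + strand), held 10.6% of wild-type reads. Its values were 106184, 1280, 22065 and 36855 RPM, 83.0-fold lower without SigJ and 4.81-fold lower without SigC. Next came Npun_F0676 (TSS 799654), with 13640, 102, 33151 and 46.5 RPM.

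The start site of the sigC gene was nearly lost without SigJ. This TSS, 69 nt upstream of the coding region, had 6251 RPM in the wild type and 21.8 RPM in the sigJ deletion, 286-fold lower (248 to 332), against 3733 RPM in the sigF deletion. In the sigC deletion the same TSS had 13253 RPM, 2.12 times the wild type (2.10 to 2.14). This site lies outside the coding region, so its reads said nothing about the deletion itself. The only assigned TSS of rpoD, the gene of the main sigma factor, was weak and stayed within 2-fold in all strains (7.21, 6.92, 4.15 and 5.10 RPM). Its counting intervals reached 2.76-fold lower without SigC and 2.12-fold lower without SigF.

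Npun_R1337 stood out in the sigJ deletion. A run of 4 neighbouring TSSs within that gene was listed at 0 there and in no other deletion strain, the longest such run in the genome. Their wild-type values were 21.4, 29.4, 7.09 and 10.6 RPM, and their values in the sigC deletion were 48.9, 52.8, 48.1 and 16.6 RPM. The TSS upstream of Npun_R1337 kept 507 of 5823 RPM in the sigJ deletion, 11.5-fold lower, and had 3883 and 5289 RPM in the other deletions. The only TSS within Npun_F4811 had 20.5, 7.75 and 10.4 RPM in the first 3 libraries and was listed at 0 without SigF, while the TSS upstream of that gene had 66.8, 0, 10.5 and 7.21 RPM. These loci were looked at after the values were seen, and the annotation used here does not name sigJ or sigF. If they are the deleted genes, which it leaves open, the zeros within them would come from absent DNA and not from lost promoter activity.

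Among genes with symbols, the deepest falls without SigJ were at gvpA, modA and ebsA, and the largest rise was at psaB. The main TSS of gvpA, encoding the gas vesicle shell protein, went from 4663 to 3.64 RPM, 1282-fold lower (95% interval 903 to 1886). The TSS of ebsA, whose product takes part in pilus assembly, went from 3562 to 8.45 RPM, 422-fold lower (335 to 539). In the other direction, the TSS of psaB (Npun_R0210), encoding a photosystem I core protein, went from 14.8 to 1496 RPM, 101-fold higher (84.8 to 122).

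A TSS was called changed when the log2 ratio to the wild type, with 1 RPM added to each value, was at least 2 in size and the higher library had at least 5 RPM. By this rule 1369 TSSs (10.8%) were lower in the sigJ deletion and 648 (5.12%) were higher, upstream of 565 and 289 genes. Of the lower TSSs, 601 were listed at 0. Together the lower TSSs held 42.1% of the wild type's listed reads, with the TSS inside Npun_F5190 (106184 RPM) the largest single part. They held 2.28% of those in the sigJ deletion, a share that the rule itself keeps small. The strongest sites were called lower most often: 38.8% of the 472 TSSs at 200 RPM or more in the wild type, against 7.12% of the 6233 below 12 RPM. The rule itself makes such calls rarer among weak TSSs. With 1 RPM added and a smallest listed value of 1.06 RPM, the weakest could be called lower only from a listed 0. The median log2 ratio of all TSSs was 0.12, and 52.7% stayed within 2-fold.

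The other genes with symbols that fell most without SigJ had varied roles. The gas vesicle, polysaccharide and cell division lists did not stand out from matched lists as groups against the wild type. Of the cell wall and division genes, the only TSS of ftsE, part of the division apparatus, went from 167 RPM to a listed 0 (at least 158-fold lower), and the main TSS of mreC, a rod-shape gene, fell from 595 to 8.80 RPM, 67.6-fold (53.8 to 86.1), or 12.5-fold over its 3 TSSs. For the hormogonium surface and motility, hpsA, a pilin-like gene of the polysaccharide locus, had 58.5 RPM and was listed at 0 (at least 55.4-fold). Npun_R0118, in a type IV pilus region, went from 251 RPM to a listed 0 (at least 238-fold), and pilM, for the inner-membrane pilus complex, from 535 to 64.8 RPM (8.25-fold). The only TSSs of 4 further genes were listed at 0: modA, a molybdate-binding protein on pNPUN01 (696 RPM, at least 659-fold), yidD, of membrane protein insertion (84.1 RPM, at least 79.6-fold), dprA, which handles incoming DNA in natural competence (40.4 RPM, at least 38.2-fold), and acpP, an acyl carrier protein (38.9 RPM, at least 36.9-fold). A pair of genes lost 1 of 2 start sites: mrdA, a penicillin-binding protein of wall elongation (75.8 RPM, at least 71.8-fold), kept 55.0 of 119 RPM in all, and pyrF, of pyrimidine synthesis (20.9 RPM, at least 19.8-fold), rose from 51.4 to 127 RPM in all through its other TSS.

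Of the 8 largest rises without SigJ at genes with symbols, 4 were at photosystem genes. Only 71 of the 289 genes with a higher TSS had a symbol. After psaB came psbH, a photosystem II subunit (93.9 to 1091 RPM, 11.6-fold, 10.8 to 12.5), and psbP, which attaches to the oxygen-evolving side of photosystem II (8.77 to 83.3 RPM, 9.50-fold, or 5.63-fold over both its TSSs). A psaK gene (Npun_F4580) of photosystem I rose 8.31-fold, from 171 to 1417 RPM. A TSS of the electron-transfer enzyme gene petH rose 9.03-fold (24.3 to 219 RPM), one of the chlorophyll synthesis gene chlP 8.97-fold (27.4 to 246 RPM) and one of the Calvin cycle phosphatase gene glpX 12.1-fold (7.57 to 91.5 RPM). Over all their TSSs these genes had smaller rises, petH 4.66-fold, chlP 5.11-fold and glpX from 14.9 to 104 RPM. The transposase gene tnpC rose 10.9-fold, from 5.41 to 59.2 RPM.

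**Figure D1:**
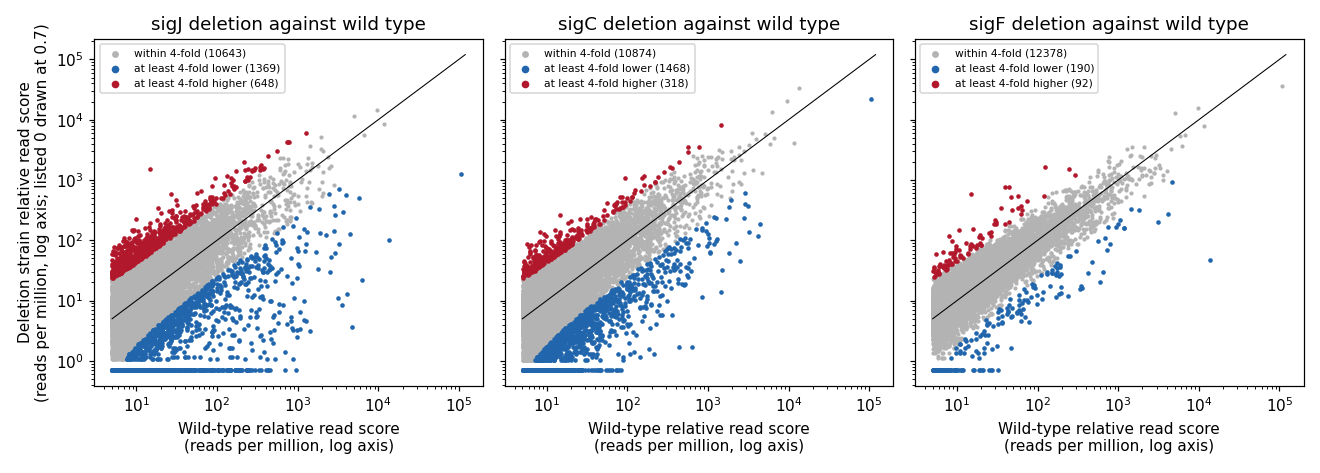
Value of each TSS in each deletion strain (vertical axis, RPM, log scale) against the wild type (horizontal axis, RPM, log scale). The sigJ, sigC and sigF panels have 1369, 1468 and 190 TSSs lower and 648, 318 and 92 higher.

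**Figure D2:**
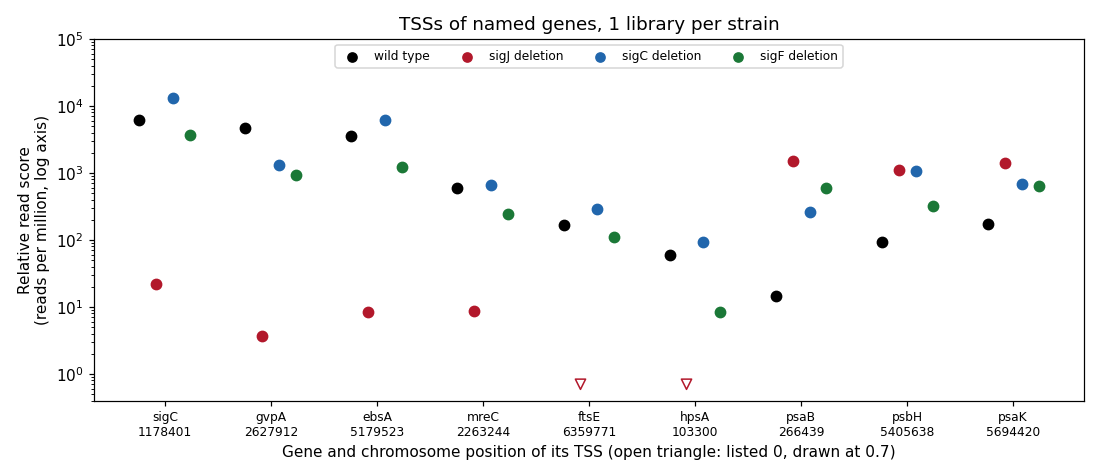
Values in the 4 libraries (RPM, log scale) of the TSSs of named genes. The gvpA TSS went from 4663 RPM in the wild type to 3.64 RPM without SigJ, and the psaB TSS from 14.8 to 1496 RPM.

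Among genes with symbols, the deepest fall without SigC was at scpB and the largest rises were at psaB and psbH. The TSS of scpB, whose product helps chromosomes separate, fell 58.4-fold (31.6 to 122) from 75.8 RPM. That of cysK, for cysteine synthesis, went from 45.2 to 1.82 RPM, 24.9-fold lower (14.6 to 45.9). The psaB TSS rose again, from 14.8 to 262 RPM (17.7-fold), and psbH from 93.9 to 1069 RPM (11.4-fold).

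By the same rule 1468 TSSs (11.6%) were lower without SigC and 318 (2.51%) higher, upstream of 440 and 182 genes; 564 of the lower ones were listed at 0. The lower TSSs held 30.9% of the wild type's listed reads, again with the TSS inside Npun_F5190 (106184 RPM) as the largest single part. They held 4.96% of those in the sigC deletion, a share that the rule itself keeps small. At 200 RPM or more in the wild type, 23.9% of TSSs were lower, and below 12 RPM 9.13%, where the rule again limits such calls. The median log2 ratio was -0.15, and 58.3% of TSSs stayed within 2-fold.

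Genes that lost their only or main TSS without SigC included tatC, of the twin-arginine export channel, which went from 20.5 RPM to a listed 0 (at least 19.8-fold). Amino acid and wall precursor genes were alr, alanine racemase (78.6 to 4.93 RPM, 15.9-fold, or 9.18-fold over both its TSSs), and dapA, of lysine and diaminopimelate synthesis (144 to 10.9 RPM, 13.2-fold). The acpP TSS fell 18.7-fold to 2.08 RPM, and pglZ, of a phage defence family, 20.4-fold (31.8 to 1.56 RPM). The scpB gene as a whole kept 24.9 of 109 RPM through its other TSS. In the gas vesicle locus gvpN, an ATPase gene of vesicle assembly, went from 379 to 34.9 RPM without SigC (10.8-fold) and to 45.5 RPM without SigJ (8.31-fold), and a weak gvpA TSS (25.0 RPM) was listed at 0 (at least 24.1-fold) while the main one kept 1331 of 4663 RPM.

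Other genes lost 1 of several start sites without SigC and changed little as a whole. These were ubiE, of quinone synthesis (18.5 RPM to a listed 0, at least 17.8-fold; 38.2 to 24.6 RPM in all), ctpB, a processing protease (12.9 RPM to a listed 0, at least 12.4-fold; 196 to 230 RPM in all), and the second psaK gene, Npun_R1705 (28.5 to 1.56 RPM, 18.3-fold; 40.8 to 27.4 RPM in all). The tRNA modification gene mnmE lost a TSS of 11.4 RPM (at least 11.0-fold) but rose from 35.6 to 79.5 RPM in all.

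The largest rises without SigC at other genes with symbols were psbP (84.2 RPM, 9.60-fold, or 5.56-fold over both its TSSs), cdf31 (8.05 to 95.5 RPM, 11.9-fold), nadA, of NAD synthesis (from 11.3 RPM, 7.97-fold), metG, methionyl-tRNA synthetase (5.41 to 41.5 RPM, 7.68-fold), dps, an iron-storing DNA-binding protein (31.4 to 228 RPM, 7.29-fold, or 4.03-fold over both its TSSs), and trxA, thioredoxin (559 to 3512 RPM, 6.28-fold). Npun_F4440 and Npun_F6046 were called lower without SigC, less than 2-fold lower in the other strains, and chosen after the values were seen: 293, 179, 30.1 and 1215 RPM for the first, and 257, 276, 39.2 and 426 RPM for the second.

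TSSs inside genes and antisense to genes fared differently from those upstream of genes when SigC was missing. The median log2 ratio was 0.13 upstream, -0.39 inside, -0.30 antisense and -0.07 elsewhere. The same medians were 0.17, -0.01, 0.16 and 0.15 without SigJ, and 0.15, 0.14, 0.19 and 0.23 without SigF.

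Loss of SigF changed far fewer sites. Npun_F0676, the second strongest TSS of the wild type, went from 13640 to 46.5 RPM, 293-fold lower (267 to 324); it was also low without SigJ (102 RPM) but had 33151 RPM without SigC. The hpsA TSS went from 58.5 to 8.43 RPM (6.94-fold) and the main gvpA TSS from 4663 to 928 RPM (5.02-fold). Npun_R0118 fell 4.64-fold, to 54.1 RPM. A TSS of the protease gene clpP (Npun_F0850) went from 114 to 10.5 RPM (10.8-fold, 8.76 to 13.5), but its 6 TSSs together kept 673 of 701 RPM. The only called rises at genes with symbols were psaB (588 RPM, 39.8-fold), the lysine synthesis gene dapB (44.2 to 204 RPM, 4.61-fold) and the fatty acid synthesis gene fabZ (11.8 to 50.5 RPM, 4.29-fold).

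In all, 190 of the 12660 TSSs were lower without SigF and 92 higher, upstream of 93 and 41 genes, and 63 were listed at 0. The lower TSSs held 6.61% of the wild type's listed reads and 0.721% of those in the sigF deletion, the latter kept small by the rule. At 200 RPM or more in the wild type 5.72% of TSSs were lower, and below 12 RPM 0.963%, with the same limit. The median log2 ratio was 0.17, and 83.6% of TSSs stayed within 2-fold.

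A single stretch of the chromosome held 65 of the 190 TSSs lower without SigF (34.2%) and 25 of the 63 listed at 0. It ran from 3199057 to 3271383, 72.3 kb with 91 genes from Npun_F2567 to Npun_R2637 and 79 TSSs on both strands (36 and 43). Their median log2 ratio was -2.78 without SigF (quartiles -3.19 and -2.29), against -0.45 without SigJ and -0.56 without SigC. The summed values were 4239, 2726, 2811 and 382 RPM, so the sigF deletion kept 9.01% of the wild type. Just outside, the TSS before it went from 10.2 to 8.43 RPM and the TSS after it from 32.6 to 63.5 RPM. Its strongest site, upstream of Npun_F2635, had 795, 917, 657 and 86.5 RPM. The stretch was found by scanning after the values were seen and was bounded as an unbroken series of TSSs at least 2-fold lower; without it 125 TSSs were lower in the sigF deletion.

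**Figure D3:**
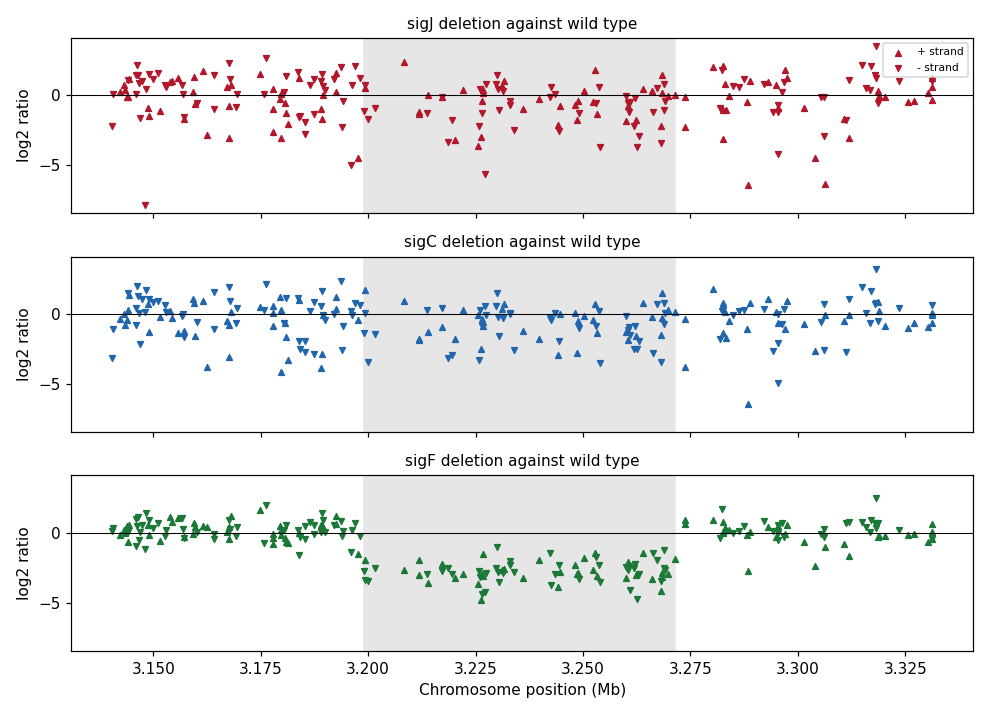
Log2 ratio of each TSS to the wild type (vertical axis, 1 RPM added) along the chromosome (horizontal axis, position in Mb) around the 72.3 kb stretch. Its 79 TSSs had a median of -2.78 without SigF.

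The overlap of the calls asked whether the same TSSs changed in several strains. Without SigJ and without SigC, 763 TSSs were lower in both, against 159 if the calls were independent. SigJ and SigF shared 129 (20.5), SigC and SigF 63 (22.0), and 57 were lower in all (2.38). Thus 67.9% of the TSSs lower without SigF were also lower without SigJ. Leaving out the 72.3 kb stretch, 114 of 125 were, with 51 shared by SigC and SigF and 48 by all. Higher in both were 230 TSSs for SigJ and SigC (16.3), 61 for SigJ and SigF (4.71) and 32 for SigC and SigF (2.31), with 31 in all. Each ratio used the same wild-type library, which could not be split, so part of this sharing may come from that library. A shared fall can also be indirect, since the sigC TSS itself fell 286-fold without SigJ. Of the TSSs lower than in the wild type, 846 of the sigJ set (61.8%), 1051 of the sigC set (71.6%) and 450 of the 763 shared (59.0%) were also lower than in the sigF deletion.

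Named sites showed several of these combinations. Lower in all strains were Npun_F0296 (4128, 12.7, 119 and 272 RPM), Npun_ER021 on pNPUN05 (3126, 11.0, 372 and 202 RPM), Npun_R6196 (1187, 9.74, 86.9 and 161 RPM), a site inside Npun_F0121 (1812, 32.9, 61.8 and 324 RPM) and an unassigned chromosomal site at 6308949 (1436, 3.17, 13.8 and 326 RPM). Lower without SigJ and without SigC, but less than 2-fold lower without SigF, were 593 TSSs, among them Npun_F1148 (4463, 126, 189 and 3306 RPM) and Npun_R5986 (2882, 61.9, 406 and 1571 RPM). The same for SigJ and SigF, but not SigC, held for 52, among them Npun_F5464 (1193, 4.70, 1361 and 158 RPM) and Npun_R2893 (992, 3.29, 739 and 183 RPM). Called in the sigJ deletion, with neither other strain even 2-fold lower, were 226 TSSs, such as Npun_F4145 (1261, 4.58, 1363 and 690 RPM) and Npun_R1551 (1082, 3.40, 891 and 706 RPM). A further 35 TSSs were lower without SigJ and at least 2-fold higher without SigC. The TSSs named for the pairs and for SigJ alone were chosen after the values were seen, from the stronger upstream TSSs of each kind.

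Photosystem genes were higher as a group in every deletion library than in the wild-type library. For 29 measured genes the median log2 ratio of summed upstream values was 1.61 without SigJ, 1.25 without SigC and 0.73 without SigF. These lay at percentiles 99.99, 99.96 and 99.97 of 10000 lists matched on mean level. At least 2-fold higher were 19, 17 and 11 genes, and at least 4-fold higher 12, 8 and 1. Against the sigF library in place of the wild type, the sigJ median lay at percentile 100 and the sigC median at 80.7, so the single wild-type library may carry the difference for SigC. For SigF no comparison free of the wild type was made. Members were the photosystem I genes psaC (736, 4339, 2338 and 2050 RPM) and psaA (399, 1558, 937 and 773 RPM) and the photosystem II genes psbZ (606, 3560, 2467 and 1359 RPM), psbM (356, 1745, 1572 and 792 RPM) and psbE (381, 1579, 1333 and 635 RPM). A psb34 gene (Npun_R6596) was the only one called lower, with a log2 ratio of -2.11 without SigJ. Of the antenna genes apcA (47.1, 259, 130 and 72.1 RPM) and apcB (174, 482, 320 and 265 RPM), only apcA without SigJ passed the 4-fold rule. NADH dehydrogenase-like and cytochrome genes (17 measured) had medians of 0.79, 0.62 and 0.12.

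The hmp locus, which encodes the chemotaxis-like system that switches on gliding, had 4 measured genes with hmpF, of which 2 were called lower without SigJ, 3 without SigC and 0 without SigF. Their median log2 ratios were -2.35, -2.30 and 0.04 for SigJ, SigC and SigF. They lay at percentiles 2.47, 0.51 and 42.8 of matched lists, and against the sigF library the sigJ and sigC medians lay at 2.65 and 1.24. The list leaves out a site just inside Npun_F5962, stronger in the wild type than any counted site. That site was called lower without SigJ only, and it fell more without SigF than without SigC. The medians therefore do not describe the whole locus, and the values of this site are given under Other observations. The hmpF values were 320, 39.0, 58.9 and 149 RPM, those of Npun_F5961 879, 225, 195 and 968 RPM, and those of Npun_F5963 35.2, 4.46, 4.02 and 33.5 RPM. Npun_F5960 (7.57, 7.16, 7.01 and 12.3 RPM) hardly moved without SigJ or SigC and was 1.63 times the wild type without SigF (1.18 to 2.25), which was not called. The first gene of the phototaxis region ptx, Npun_F2161, had 81.4, 3.99, 12.8 and 52.7 RPM. Polysaccharide (hps) genes did not stand out as a group against the wild type: the median of 11 was -0.28, 0.25 and -0.04 (percentiles 19.5, 60.3 and 25.2; sigJ against the sigC library 0.74), with 3 called lower without SigJ and 1 in each other strain. Among them hpsJ-B had 334, 64.1, 142 and 326 RPM, hpsL 6.01 RPM in the wild type and a listed 0 without SigJ and without SigC, and Npun_F0076, which was not called, 40.0, 123, 114 and 61.7 RPM.

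Cell division and shape genes (15) had medians of -0.43, -0.58 and -0.14 (percentiles 5.65, 2.49 and 8.80), with 3, 1 and 0 genes called lower. Against the wild type only the sigC median reached the lowest 2.5% of matched lists, and it lay on the edge of that range. Against the sigF library the sigJ and sigC medians lay at percentiles 1.07 and 2.20. The division ring gene ftsZ had log2 ratios of -1.36, -1.87 and -0.10, rodA reached -2.42 without SigJ and murI -2.43 without SigC, and minD 1.76 without SigJ, which was not called. The gas vesicle genes (3) had medians of -3.03, -1.82 and -0.70 (percentiles 10.2, 5.25 and 21.2). Chaperone genes (16) had -0.33, -0.23 and -0.12, with dnaK (Npun_F0567) at 523, 94.8, 108 and 303 RPM and groES at 961, 234, 195 and 496 RPM.

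Ribosomal protein genes (33) had medians of -0.02, 0.02 and -0.03 but went both ways: 8 were at least 2-fold lower and 4 higher without SigJ, 5 and 6 without SigC, and 1 and 3 without SigF. Among them rplA fell by 2.69 on the log2 scale without SigJ (25.2 to 3.05 RPM), and rpsJ had 236, 49.6, 44.2 and 93.4 RPM. Against the sigC library the sigJ median of the ribosomal list was -0.32, at percentile 0.96 of matched lists. Nitrogen fixation and heterocyst genes (10) had -0.19, -0.25 and -0.09. Of these hetZ and devC, which act in early and late heterocyst development, were listed at 0 without SigJ, from 15.1 and 7.33 RPM, and hetF, a protease-like regulator, had 195, 99.2, 67.5 and 137 RPM. The master regulator hetR, named after its values were seen, kept 60.4, 76.4, 52.0 and 67.5 RPM. Two-component genes (5) had medians of 0.73, 0.70 and 0.30, with nblR, of phycobilisome degradation and stress responses, at 80.6, 305, 177 and 165 RPM. Transposase genes (3) had 1.37, 1.28 and 0.89.

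**Figure D4:**
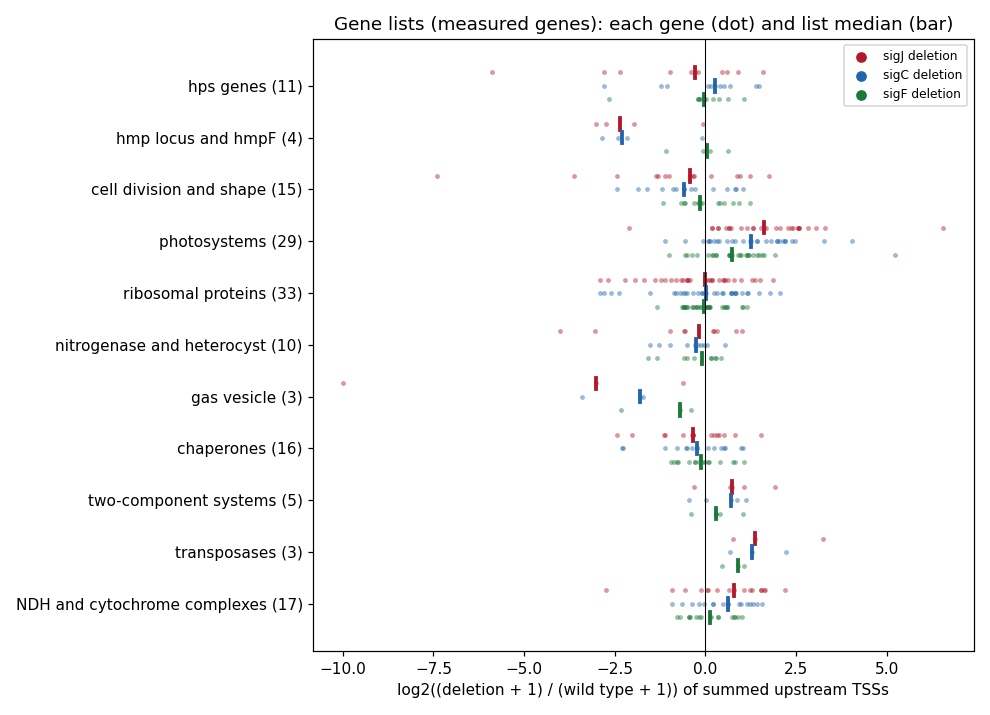
Median log2 ratio to the wild type of the measured genes of each list (horizontal axis, 1 RPM added to summed upstream values) for the sigJ, sigC and sigF deletions. Photosystem genes had 1.61, 1.25 and 0.73, and the hmp locus -2.35, -2.30 and 0.04.

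The balance of falls and rises depended on scaling. Lower TSSs made up 67.9% of the calls without SigJ with the values as listed, 79.8% after rescaling by the median of ratios (1586 lower, 401 higher) and 82.5% after leaving out the strongest 1% of TSSs from the totals (1639 lower, 347 higher). For SigC the shares were 82.2%, 77.6% and 88.3%, and for SigF 67.4%, 76.0% and 78.5%. Because TSSs were listed only at 5.05 RPM or more in the wild type, sites used only in a deletion strain could not be seen, which favours falls over rises. With a fold of 2 in place of 4, rises outnumbered falls without SigJ (3034 and 2955) and without SigF (1305 and 771). The median of the hmp locus without SigF became -0.12 after rescaling by the median of ratios and -0.15 after leaving out the strongest 1%.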

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

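Of 115 alternatives to the counts of calls and overlaps, 58 stayed within 1.5 times the main count and 57 did not; the cause was not tested except where the alternative counts fewer items by construction. Counts below are in the order lower without SigJ, SigC and SigF, then higher. Counting genes by summed TSSs gave 410, 288 and 77, and 216, 116 and 31; the strongest TSS of each gene gave 453, 321 and 81, and 257, 165 and 39; upstream TSSs alone gave 605, 466 and 96, and 296, 185 and 41. All of these count fewer items. A fold of 2 gave 2955, 3418 and 771, and 3034, 1860 and 1305, with 2192 TSSs lower without SigJ and SigC, 615 without SigJ and SigF, 392 without SigC and SigF and 345 in all. At this fold, rises outnumbered falls without SigJ and without SigF. A fold of 8 gave 658, 580 and 63, and 79, 25 and 13, with overlaps of 230, 41, 15 and 13. A pseudocount of 5 gave 587, 495 and 92, and 404, 161 and 49, with overlaps of 281, 71, 38 and 34. A minimum of 20 RPM gave 727, 656 and 113 lower and 415 shared by SigJ and SigC.

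Rescaling by the median of ratios gave 401 TSSs higher without SigJ, and totals without the strongest 1% gave 347; the cause was not tested. A pseudocount of 0.1 kept every count within 1.5 times. Having no minimum level changed nothing by construction, since 0 TSSs lie under 5 RPM in both libraries. The following were chosen after seeing the data. Leaving out the 72.3 kb stretch gave 125 lower without SigF, by construction. Asking for a fall against the sigF library as well gave 846 lower without SigJ and 450 shared with SigC. Setting a listed 0 to the smallest listed value, or leaving out 548 TSSs within 20 nt of a stronger one, kept every count within 1.5 times. Of 33 gene list medians, the 6 in the outer 2.5% of matched lists kept their sign under every alternative. The hmp locus without SigJ (percentile 2.47) and division genes without SigC (2.49) lay at the edge of that range. With 33 medians placed, some can fall there by the draw of genes alone. Of all 198 alternatives, 8 turned the sign of 7 medians no larger than 0.19 in size, such as nitrogen fixation genes without SigJ (-0.19, or 0.33 with a minimum of 20 RPM). Against the bootstrap 95% interval over the genes of a list, 196 stayed inside and 2 did not, polysaccharide genes without SigF (-0.20) and gas vesicle genes without SigC (-1.69), both under the median of ratios. That interval is wide for short lists: with a minimum of 20 RPM the gas vesicle medians became -6.51 without SigJ and -2.61 without SigC, as 2 genes were left. No paired analysis was possible because each strain has 1 library. Promoter sequence features and their alternatives (other folds, the strongest TSS within 20 nt, other scaling) were not run, since no genome sequence was at hand. Depth limits falls of weak TSSs: one at 5.05 RPM in the wild type rests on 42 reads, and its fall cannot be followed below about 1 RPM.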

Other observations

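Several small lists had fewer than 3 measured genes. The chemotaxis gene cheB, a methylesterase of receptor adaptation, had 7.93, 4.81, 4.93 and 2.55 RPM (wild type, sigJ, sigC and sigF deletion). Of the carbon fixation genes, ccmS, of carboxysome assembly, had 5.89, 4.81, 1.95 and 9.10 RPM and rcbX, a Rubisco chaperone, had 5.05, 3.99, 7.40 and 4.77 RPM. The ATP synthase genes atpD (15.1, 25.9, 19.1 and 9.87 RPM) and atpB (7.33, 19.5, 23.5 and 9.87 RPM) were not called in any strain. TSSs lower without SigJ had a median log2 ratio of -2.33 without SigC and -0.64 without SigF.

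In the hmp locus Npun_F5961 had several start sites that behaved apart. The TSS at 7359334 was 15.1-fold lower without SigJ and 47.5-fold lower without SigC. The TSS at 7359444 was listed at 0 without SigJ (at least 20.4-fold lower) and 6.92-fold lower without SigF, but without SigC it was at or above its wild-type value. The stronger site at 7359345 was 4.62-fold lower without SigC and 3.40-fold lower without SigJ, where it was not called. A site 1 nt inside Npun_F5962, not counted in the list, had 2571, 53.8, 2130 and 1120 RPM.

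Explanations for 3 patterns were weighed. The predictions for the chromosomal stretch, and those on the wild-type library standing apart, were written after the results were seen; the others were written before.

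Loss of the DNA of the 72.3 kb stretch from most cells of the sigF culture was not decided. In the scanned run of 81 TSSs that holds it, the SD of the log2 ratios of 33 TSSs at 20 RPM or more, 0.789, was no larger than the 0.853 outside, with a slope of 0.80, but the run was chosen for its low ratios, which narrows that SD. Scattered SigF promoters did not account for the stretch, since 97.4% of 39 TSSs left out of the search were at least 2-fold below the wild type, against 5.55% outside. Mapping or filtering was not decided. The medians in the other deletions were only -0.56 and -0.45, but a loss alike in all libraries would cancel in every ratio to the wild type. A fault in the sigF library alone would leave those medians unchanged. Lower transcription of the whole stretch with its DNA in place was left open too (SD ratio 0.925).

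Between the sigC and wild-type libraries, the lower values of TSSs inside and antisense to genes were not confined to weak sites. At wild-type values of 20 to 200 RPM the difference to upstream TSSs was 0.48 (0.37 to 0.59, from resampling TSSs). That interval leaves out variation between cultures or libraries, which 1 library per strain cannot show. Ends of processed transcripts could give the part inside genes only, and there the rank correlation with the gene's own upstream TSSs was 0.108, against -0.0496 for antisense TSSs. The difference from upstream TSSs was 0.52 inside and 0.43 antisense. This left processing undecided, and no biological explanation was tested.

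The rise of photosystem genes in the sigJ library over the wild-type library was not made by the strongest wild-type TSSs taking reads. After totals without the strongest 1% the median was still 1.27 (0.65 to 2.01, from resampling the 29 genes). That interval also leaves out variation between cultures or libraries, so it covers the listed values of these libraries only. Whether selection of TSSs by wild-type level played a part was not decided: the median lay at percentile 99.99 of matched lists, but these were matched on mean level, and such selection favours falls. Set against the sigF library instead of the wild type, the sigJ median was 1.01, at percentile 100. The sigC median against the sigF library was 0.52, at percentile 80.7, so for SigC a wild-type library standing apart may account for the rise. In both comparisons with the sigF library, that library was the lower one by the median, so the sigF rise rested on the wild type alone. No biological explanation was tested.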
